A study of Mus musculus with 7 samples.

How the data were processed

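RNA from 7 samples of sorted embryonic mouse cortical cells, 4 control and 3 Trnp1 knockdown, was hybridised to 1 Affymetrix gene array each. Per the labels' protocols, total RNA was prepared with DNase treatment, and labelled after whole-transcriptome amplification, a step used for small amounts of RNA that can add spread between samples. The deposited values are on the log2 scale and lie between 1.97 and 13.7. They were made with RMA in Affymetrix Expression Console 1.2, per the submitters' processing notes. RMA corrects the background, normalizes the arrays by quantiles of their probes and summarises the probes of each set, so it removes overall differences in brightness and compresses differences of dim probe sets. The genome build behind the array annotation is not given in the sources used here. Replicates were not pooled, and each column was matched to its sample by its name.

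The table held 35556 probe sets. A table of array annotation gave 1 gene symbol for 21789 of them, several for 1621 and none for 12146. Symbols were looked up through Entrez gene identifiers in a RefSeq gene table of assembly GRCm38.p6, where 21698 of the probe sets with 1 symbol matched. That table served for names only, so no coordinates are printed. Each gene was represented by the probe set with the highest mean over all 7 arrays, among those with exactly 1 symbol, which left 19938 genes, of which 999 had more than 1 probe set. A gene without such a probe set was not analysed here. No pair of arrays held identical values, and correlations between arrays over all probe sets, which are not independent replicates, lay between 0.937 and 0.976. For arrays no count depth applies, and the number of arrays limits the precision.

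Knockdown was compared with control by limma 3.58.1 in R 4.3.3, with lmFit and eBayes without trend, over all 7 arrays and without covariates. The test was two-sided with 5 residual and 2.36 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Standard errors (SE) and 95% intervals of log2 differences are those of limma. Trnp1 and the list scores were also tested by an exact two-sided permutation test of the difference of group means over the 35 splits of the arrays into 4 and 3. The labels call the samples biological replicates and do not say how many animals each holds. Replicate numbers 1 to 3 occur in both groups and are not said to mark a shared litter or day, so the comparison has no block.

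The 40 gene lists were written before the data were examined, from textbook knowledge of the cell types, pathways and complexes of the embryonic cortex and of knockdown experiments, and hold 784 distinct measured genes. They were tested by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists, and beside it by camera with an estimated correlation and by fry. Camera asks whether the genes of a list differ more than other genes, and fry whether they move on balance in 1 direction or, in its mixed form, in either. For each list the members past the threshold were counted over all genes and adjusted over the list alone. As a description, each list's median was set against 10000 random lists of the same size, drawn from 20 bins of mean level. A list's score in an array is the mean over its genes of the log2 difference from the control mean.

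The rule for the named genes was also fixed before the data were examined. It takes Trnp1, the 12 genes with the largest change in each direction among those that passed with groups that do not overlap, filled up to 12 with the smallest unadjusted p, and from each described list up to 4 members with the smallest p, and for cell type lists also up to 4 with the highest level. As no gene passed, the named genes are those with the smallest p. Clone names and small RNA genes were passed over. Which lists are described was chosen after the results were seen, namely all lists that passed and 6 that bear on progenitors, neurons, S phase and Polycomb genes.

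The fits were tested on simulated data with the gene means and spreads of the 7 arrays. In 5 runs over 19938 genes, 200 of them changed, limma recovered 48.4% of genes changed by 1 log2 unit and 82.8% of those changed by 2, with 8 false calls per run. A list shifted by -0.5 log2 units was called in all 5 runs, and 1 list that was not shifted was called over all runs. The simulation draws genes independently, unlike real samples, in which genes of a list vary together.

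The alternatives fixed beforehand were an intensity trend, a robust prior, array weights, equal array medians, a further quantile normalization, the dimmest 25% or 50% of genes left out, the mean over a gene's probe sets, every probe set on its own, the replicate number as a block, each array left out in turn, an adjusted p under 0.1, a minimum of 1.5-fold, camera with an estimated correlation, and fry. Added after the data were seen were cyclic loess normalization between the arrays, the endothelial list score as a covariate, and control replicate 4 and knockdown replicate 3 left out together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.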

Results

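Gene expression was measured on 7 Affymetrix arrays in cells sorted from the embryonic mouse cerebral cortex (strain C57BL/6). Cortices were electroporated on embryonic day 13 with constructs carrying green fluorescent protein, and the fluorescent cells were isolated by flow cytometry 24 h later, on embryonic day 14. In 3 samples the construct lowered Trnp1, a nuclear protein of cortical progenitors, and the other 4 samples were controls, each labelled as a biological replicate. The comparison asks which transcripts differ in cortical cells 1 day after Trnp1 is knocked down. The array medians over all 35556 probe sets lay between 4.398 and 4.611 on the log2 scale, and the number of arrays limits the precision of every value.

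Trnp1 itself (Entrez 69539) was measured by a probe set at the 51.4th percentile of mean level among the genes. Its log2 level was 5.13 ± 0.117 (SD, n = 4) in controls and 4.73 ± 0.159 (SD, n = 3) in knockdown samples. All 3 knockdown arrays (4.80, 4.85 and 4.55) lay below all 4 control arrays (5.07, 4.999, 5.24 and 5.22), in the direction of the labels. The difference was -0.40 (SE 0.12, 95% interval -0.69 to -0.11), so the knockdown signal was 75.8% of the control signal (62.1% to 92.4%). RMA compresses differences of dim probe sets, and this one had a mean level of only 4.96. The fall of the transcript itself may therefore be larger than this percentage. The exact two-sided permutation test over the 35 splits of the arrays gave p = 0.0286, the smallest p that these splits can give, and limma's adjusted p over all genes was 0.825.

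**Figure D1:**
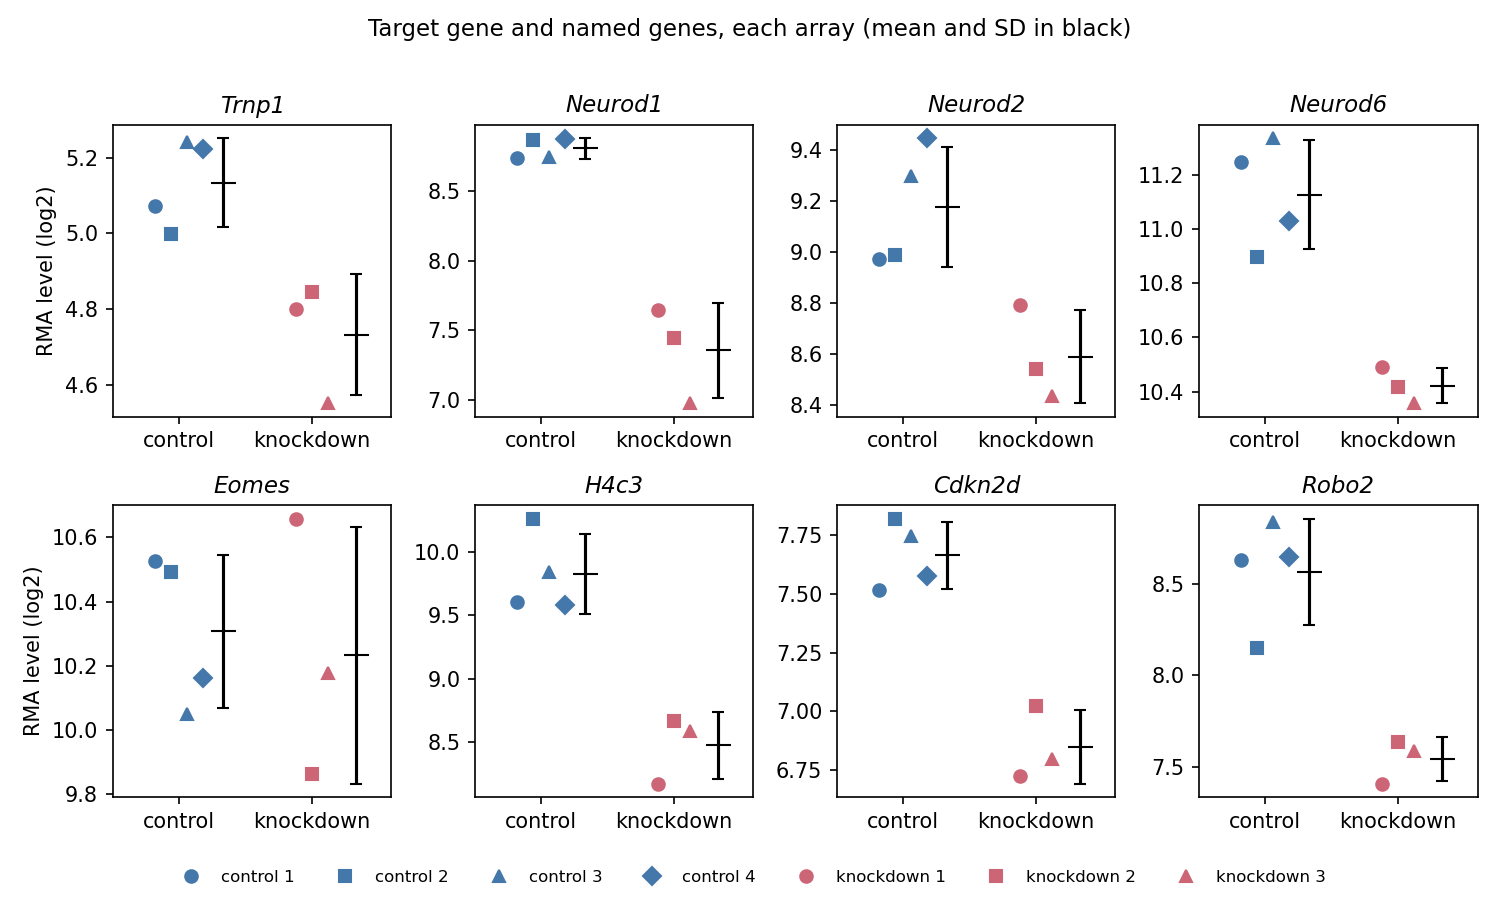
RMA level (log2, vertical axis) of Trnp1 and 7 other genes in each control array (blue) and knockdown array (red), with the group mean and SD in black and a marker shape for each replicate number. Trnp1 lay between 4.999 and 5.24 in the controls and between 4.55 and 4.85 in the knockdown samples, whereas the groups overlapped for Eomes, whose difference of -0.07 changed sign after a further quantile normalization (0.05).

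No single gene passed the test over all genes, and the genes with the smallest p had varied functions. Neurod1 (Entrez 18012), a basic helix-loop-helix factor of neuronal differentiation, had the smallest p of all genes, with a log2 level of 8.80 ± 0.0729 (SD, n = 4) in controls and 7.36 ± 0.343 (SD, n = 3) in knockdown samples, a difference of -1.45 (SE 0.17) or 2.73-fold. The related factors Neurod6 and Neurod2 differed by -0.71 (SE 0.13) and -0.59 (SE 0.16). Of the fixed gene lists, replication-dependent histones fell most clearly, and glycolysis and hypoxia genes rose, by limma's camera with its preset inter-gene correlation (adjusted p = 1.16e-10 and 1.64e-05). Neither list passed with a correlation estimated from the arrays (adjusted p = 0.586 and 0.648 with an estimated correlation).

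By limma, 0 of the 19938 genes tested had an adjusted p under 0.05 in either direction, and the smallest adjusted p was 0.736. At an unadjusted p under 0.05 there were 439 genes higher and 719 lower in knockdown samples, together 5.81% of the genes where chance gives 5%. The excess of lower genes depended on the scaling, with 231 higher and 1033 lower with the array medians set equal, 473 and 564 after a further quantile normalization, and 503 and 522 after cyclic loess normalization. With an intensity trend the counts were 501 and 587, and without control replicate 4 and knockdown replicate 3 together they were 800 and 541. Without knockdown replicate 2 the counts were 882 higher and 1522 lower, without knockdown replicate 1 the lower count was 469, and without knockdown replicate 3 it was 476. The groups did not overlap for 1130 genes, 5.67% of those tested, where chance gives 5.71%. The direction depended on the level: the median log2 difference was -0.16 for the 2136 genes with a mean level over 8 and 0.03 for the 7050 genes under 4.

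The 12 lower genes with the smallest p did not pass the test. For each of them all knockdown arrays lay below all control arrays, which a choice by smallest p favours, so it adds no support. After Neurod1 came Def8 (-0.74, SE 0.10) and Vash2, a vasohibin (-1.22, SE 0.18). Mis12, a kinetochore component, differed by -1.16 (SE 0.17), from 7.28 ± 0.133 (SD, n = 4) to 6.12 ± 0.336 (SD, n = 3). The histone gene H4c3 differed by -1.35 (SE 0.21), and Cdkn2d, an inhibitor of cyclin-dependent kinases, by -0.81 (SE 0.13). Bmi1, a subunit of Polycomb repressive complex 1, differed by -0.76 (SE 0.12) and Robo2, a receptor for Slit guidance proteins, by -1.02 (SE 0.17). The remaining genes of this rule were Fbxo46 (-0.83), Ap3s1 (-1.16), Chst15 (-1.08) and Tspan14 (-0.66).

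The 12 higher genes with the smallest p did not pass either, and their groups did not overlap, which the choice by p again favours. The largest of these differences was that of Meg3, an imprinted long non-coding RNA, whose log2 level was 7.74 ± 0.290 (SD, n = 4) in controls and 9.76 ± 0.867 (SD, n = 3) in knockdown samples (2.02, SE 0.38). Ndufa4l2, a mitochondrial protein induced by low oxygen, differed by 1.97 (SE 0.43), and the heat shock gene Hspa1a, which has a near-identical copy in Hspa1b, by 1.85 (SE 0.37). D11Wsu47e had the smallest p among the higher genes (1.17, SE 0.17, adjusted p = 0.736 by limma). The cadherin Cdh6 differed by 0.89 and the diacylglycerol kinase Dgkh by 0.79, while Caprin2 (0.84), Ushbp1 (0.85), Slpi (0.64), Slc9a8 (0.62), Zcchc12 (0.59) and Pgap4 (0.68) were the others. One clone-named transcript was passed over in this direction.

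Replication-dependent histones, which are made in S phase to package new DNA, fell as a list in knockdown samples. Of the 45 histone genes written in the list, 20 were measured and the others were not analysed. The list's mean log2 difference was -0.48 over these 20 genes, with 18 members lower and 2 higher. The adjusted p was 1.16e-10 by camera (adjusted p = 0.586 with an estimated correlation), and the list's score in each array gave p = 0.0286 by the exact permutation test. No histone gene passed over all genes, and 9 passed, all lower, when adjusted over the list alone. H4c6 differed by -0.91 (SE 0.17), H4f16 by -0.83 (SE 0.15) and H2bc14 by -0.55 (SE 0.15), the last from a high control level of 11.8. Histone genes of a family resemble each other closely, so their probe sets can share signal and are not independent.

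**Figure D2:**
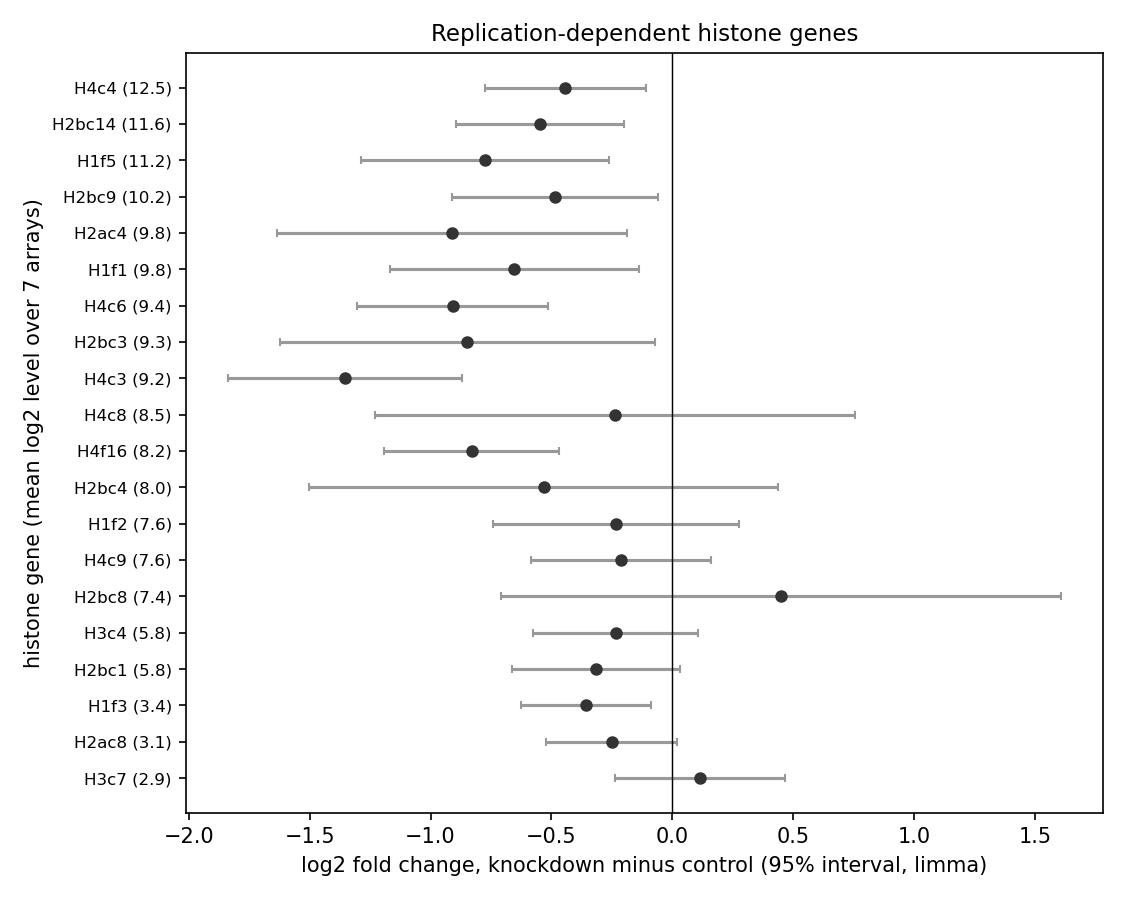
Log2 fold change of each measured replication-dependent histone gene (knockdown minus control, horizontal axis, with limma's 95% interval), ordered by the mean log2 level given beside its name. Of the 20 genes 18 lie below 0, and H4c3 is the lowest at -1.35.

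Genes of cell cycle exit fell as a list, by a mean of -0.26 over 14 genes with 10 members lower (adjusted p = 0.00773 by camera, and adjusted p = 0.586 with an estimated correlation). When adjusted over the list alone 3 members passed, all lower, and over all genes 0 did, and the call ended after a further quantile or a cyclic loess normalization (means -0.17 and -0.16). The list's median of -0.22 lay at percentile 7.42 of random lists of the same levels, whose median was -0.10, so the list did not stand clearly apart from them. Besides Cdkn2d, the lowest p values belonged to the kinase inhibitor Cdkn1b (-0.63, SE 0.16), the retinoblastoma gene Rb1 (-0.62, SE 0.18) and the antiproliferative factor Tob1 (-0.46, SE 0.17, and -0.26 without knockdown replicate 3). Genes of G2 and M phase also fell as a list, with all 31 members lower and a mean of -0.54 (adjusted p = 4.71e-06 by camera, and adjusted p = 0.716 with an estimated correlation). Cdk1, the mitotic kinase, differed by -0.95 (SE 0.33), and Prc1, Hmmr and Ttk by -0.81, -1.28 and -0.79, but no member passed over all genes or when adjusted over the list alone. The G2 and M phase call ended without knockdown replicate 1 (mean -0.16), and without knockdown replicate 2 the mean was -0.92. Prc1 and Ttk differed by -0.44 and -0.37 without knockdown replicate 1, and Prc1 and Hmmr by -1.22 and -1.95 without knockdown replicate 2. S phase genes did not pass as a list (mean -0.12 over 29 genes, adjusted p = 0.201 by camera), and the mean was 0.0015 after a further quantile normalization. This list passed as lower without control replicate 4 (mean -0.23) and without knockdown replicate 2 (mean -0.26), and its mean was 0.018 without control replicate 2, -0.036 without knockdown replicate 1 and -0.046 without knockdown replicate 3.

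The neuronal list did not move as a whole, with 11 of 23 members higher and 12 lower (mean -0.03, adjusted p = 0.193 by camera). When adjusted over the list alone, 3 members passed as lower and 1 as higher, and over all genes 0 did. Beside the Neurod genes, Dcx, which encodes the microtubule protein doublecortin, differed by -0.52 (SE 0.19), whereas the synaptic vesicle gene Syt1 differed by 1.12 (SE 0.31), and by 0.72 without knockdown replicate 3. Tubb3, a neuronal tubulin, differed by -0.50 (SE 0.28), within the spread of the knockdown arrays, and by -0.12 and -0.75 without knockdown replicates 1 and 2. The list's direction rested on single arrays: its score was -0.44 in knockdown replicate 1, -0.17 in replicate 2 and 0.50 in replicate 3, and the list passed as lower without knockdown replicate 3 (mean -0.30). The mean was 0.17 without knockdown replicate 1, 0.032 without knockdown replicate 2, 0.0013 without control replicate 3, -0.079 without control replicate 1 and -0.013 without control replicate 4, and 0.084 after a further quantile normalization.

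Genes of neuronal migration and axon guidance went both ways, with 15 of 26 lower and 11 higher (mean -0.10, adjusted p = 0.303 by camera). When adjusted over the list alone 4 members passed as lower and 3 as higher and over all genes 0 did. The semaphorin co-receptor Nrp1 differed by -1.37 (SE 0.31), the small GTPase Rnd2 by -1.24 (SE 0.29) and the plexin Plxna4 by -0.69 (SE 0.17). The list of DNA methylation, Polycomb and histone methylation genes did not pass (mean -0.10, 16 of 24 lower, adjusted p = 0.211 by camera). In it 1 gene, lower, passed when adjusted over the list alone, and the Polycomb genes Rnf2 and Suz12 differed by -0.60 (SE 0.20) and -0.45 (SE 0.16), while 0 members passed over all genes. This list passed as lower without control replicate 4 (mean -0.16), and its mean was -0.058 without control replicate 2, -0.068 without knockdown replicate 3 and 0.0059 after cyclic loess normalization. The mean of the axon guidance list was -0.03 without knockdown replicate 1 and 0.00044 after a further quantile normalization.

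Markers of intermediate progenitors, the basal dividing cells that produce cortical neurons, were lower as a list by camera (mean -0.17, 14 of 20 lower, adjusted p = 0.021 by camera, and adjusted p = 0.648 with an estimated correlation). The list's median of -0.20 lay at percentile 19.5 of random lists of the same levels, whose median was -0.14, so most of this difference was shared by genes of like level. The transcription factors Eomes and Neurog2, which define these cells, differed by only -0.07 (SE 0.22) and 0.02 (SE 0.31), and both changed sign when 1 array was left out, Eomes to 0.11 without knockdown replicate 2 and Neurog2 to -0.18 without knockdown replicate 1, -0.15 without knockdown replicate 3 and -0.12 without control replicate 4. Rasgef1b differed by -0.94 (SE 0.21) and the somatostatin receptor Sstr2 by -0.65 (SE 0.20), while the chromatin remodeller Chd7 differed by 0.61 (SE 0.23). Over all genes 0 members passed, and 1, lower, passed when adjusted over the list alone. The call ended without control replicate 1 (mean -0.16), control replicate 2 (-0.13), knockdown replicate 2 (-0.14) or knockdown replicate 3 (-0.13), and after a further quantile or a cyclic loess normalization (-0.056 and -0.046). Radial glia, the apical stem cells of the cortex, did not differ as a list (mean -0.09, 16 of 24 lower, adjusted p = 0.252 by camera), and this mean was 0.035 after a further quantile normalization. Their abundant genes Fabp7 and Vim differed by 0.23 (SE 0.20) and 0.29 (SE 0.17), while Emx1, a dorsal cortical factor, differed by -0.36 (SE 0.12, and -0.23 without knockdown replicate 2) and Prom1 by -0.47 (SE 0.17). The value of Fabp7 was 0.13 without control replicate 3 or 4 and 0.36 without knockdown replicate 1. The list passed as lower without control replicate 4 (mean -0.18), and its mean was -0.17, -0.018 and -0.0015 without knockdown replicate 1, control replicate 2 and knockdown replicate 3. The radial glia median of -0.045 lay at percentile 95.1 of random lists of the same levels. Their median was -0.15, so over all arrays radial glia genes were not low for their level. Genes typical of basal radial glia in species with folded cortices did not pass either (mean 0.15, 10 of 16 higher, adjusted p = 0.328 by camera). Among them Egln3, which is also in the glycolysis and hypoxia list, had the smallest p and differed by 1.29 (SE 0.40). Ptprz1 differed by 0.69 (SE 0.37) and Hopx by -0.20 (SE 0.22). The value of Hopx ranged from -0.37 to -0.082 with 1 array left out, lowest without control replicate 4 and highest without knockdown replicate 3. The mean of the basal radial glia list was 0.049 without control replicate 3 and 0.23 without control replicate 4. No member of the S phase, radial glia or basal radial glia lists passed, over all genes or when adjusted over the list alone.

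Glycolysis and hypoxia genes rose as a list (mean 0.49, 22 of 26 higher, adjusted p = 1.64e-05 by camera, and adjusted p = 0.648 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, differed by 1.29 (SE 0.40), the mitophagy receptor Bnip3 by 1.17 (SE 0.43), the peptide hormone gene Adm by 1.61 (SE 0.59) and the lactate transporter Slc16a3 by 0.63 (SE 0.22). Without knockdown replicate 1 Adm and Bnip3 differed by 0.93 and 0.76. The list's score was 0.86 in knockdown replicate 1 and 0.72 in replicate 3 but -0.12 in replicate 2, so the mean was 0.30 without knockdown replicate 1 and 0.79 without knockdown replicate 2. Oxidative phosphorylation genes fell as a list (mean -0.26, 30 of 33 lower, adjusted p = 4.71e-06 by camera, and adjusted p = 0.651 with an estimated correlation). The respiratory chain genes Ndufa1, Ndufb3, Ndufb5 and Uqcrh differed by -0.73, -0.52, -0.64 and -0.38. The oxidative phosphorylation median of -0.27 lay at percentile 2 of random lists of the same levels. Their median was -0.16, so much of the fall was shared by genes of like level. The mean of the oxidative phosphorylation list was -0.41 without knockdown replicate 2 and -0.12 without knockdown replicate 3, and its call ended after a further quantile or a cyclic loess normalization (means -0.11 and -0.094). In neither list did a member pass, over all genes or when adjusted over the list alone. Ribosome biogenesis genes were lower as a list by camera (mean -0.17, 22 of 28 lower, adjusted p = 0.021 by camera, and adjusted p = 0.772 with an estimated correlation), with Rrn3 at -0.45 (SE 0.13) and the transcription factor of ribosomal RNA genes Ubtf at -0.31. The list's median of -0.19 lay at percentile 10.7 of random lists of the same levels, whose median was -0.11, so most of this difference too was shared by genes of like level. No member passed, over all genes or when adjusted over the list alone. The call ended without control replicate 2 (mean -0.15), control replicate 3 (-0.13) or knockdown replicate 3 (-0.036), and with equal array medians (-0.24), a further quantile normalization (-0.071) or cyclic loess (-0.063), and without knockdown replicate 2 the mean was -0.31.

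Targets of p53 fell as a list (mean -0.19, 20 of 25 lower, adjusted p = 0.0117 by camera, and adjusted p = 0.648 with an estimated correlation). Sesn1 differed by -0.54 (SE 0.13), Zmat3 by -0.71 (SE 0.18) and Trp53inp1 by -0.82 (SE 0.22), whereas the kinase gene Plk2 differed by 1.28 (SE 0.30). When adjusted over the list alone 3 members passed as lower and 1 as higher, and over all genes 0 did. The call ended without control replicate 2 (mean -0.11) and without knockdown replicate 3 (-0.088), and after a further quantile or a cyclic loess normalization (-0.13 and -0.12).

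**Figure D3:**
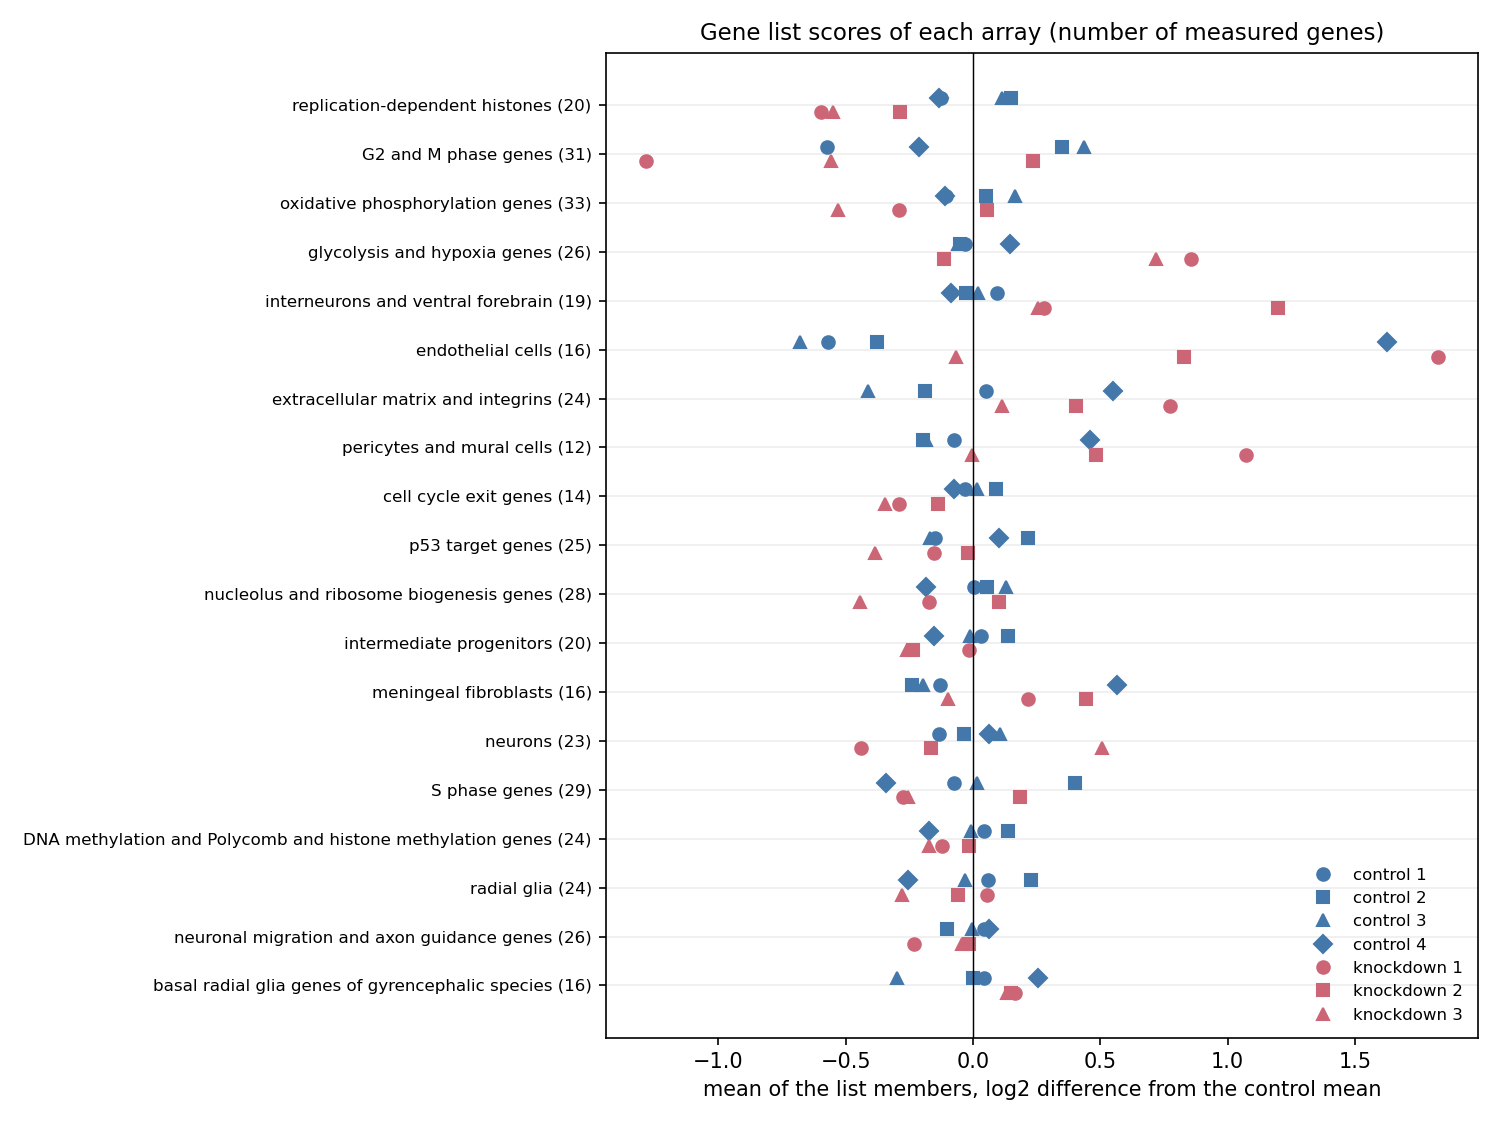
Score of 19 gene lists in each array, as the mean over the list's measured genes of the log2 difference from the control mean (horizontal axis), with controls in blue, knockdown samples in red and a marker shape for each replicate number. All 3 knockdown arrays lie below all 4 controls for the histone list, whereas control replicate 4, at 1.63, lies among the knockdown arrays for the endothelial list.

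Markers of blood vessel cells rose as lists. Endothelial markers had a mean of 0.86 with 15 of 16 higher (adjusted p = 0.000493 by camera, and adjusted p = 0.716 with an estimated correlation). Pericyte and mural markers had a mean of 0.52 with 10 of 12 higher (adjusted p = 0.00614 by camera, and adjusted p = 0.648 with an estimated correlation). The endothelial receptors Flt1 and Kdr differed by 1.43 (SE 0.73) and 1.44 (SE 0.88), the vessel glucose transporter Slc2a1 by 0.96 (SE 0.45), and the mural genes Vtn and Pdgfrb by 1.23 (SE 0.54) and 0.73 (SE 0.38). Without knockdown replicate 1 the values of Flt1, Kdr, Slc2a1, Vtn and Pdgfrb were 0.58, 0.69, 0.62, 0.69 and 0.28, and without knockdown replicate 3 those of Vtn and Pdgfrb were 1.89 and 1.10. Endothelial scores were high in control replicate 4 (1.63), knockdown replicate 1 (1.83) and knockdown replicate 2 (0.83), and the exact permutation test of the score gave p = 0.314. Both calls ended without knockdown replicate 1 (means 0.38 and 0.24), while the means were 1.33 and 0.78 without knockdown replicate 3, and the endothelial mean was 1.40 without control replicate 4. Extracellular matrix and integrin genes rose as a list with a mean of 0.43 and 20 of 24 higher (adjusted p = 0.000583 by camera, and adjusted p = 0.648 with an estimated correlation). In that list fibronectin, Fn1, differed by 1.22 (SE 0.41), and the mean was 0.26 without knockdown replicate 1. Meningeal fibroblast markers rose with a mean of 0.19 and 13 of 16 higher (adjusted p = 0.0306 by camera, and adjusted p = 0.648 with an estimated correlation). That call ended without control replicate 1 (mean 0.14), control replicate 2 (0.11), control replicate 3 (0.12) or knockdown replicate 2 (0.059), and after a further quantile or a cyclic loess normalization (0.16 and 0.17), and its mean was 0.38 without control replicate 4 and 0.33 without knockdown replicate 3. No member of these 4 lists passed, over all genes or when adjusted over the list alone.

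Interneuron and ventral forebrain genes, which mark the region beneath the cortex and the inhibitory neurons it sends out, rose as a list (mean 0.58, median 0.19, 18 of 19 higher, adjusted p = 2.13e-05 by camera, and adjusted p = 0.648 with an estimated correlation). Dlx5 had a log2 level of 4.68 ± 0.0782 (SD, n = 4) in the controls and 6.31, 8.73 and 5.40 in knockdown replicates 1, 2 and 3, a difference of 2.14 (SE 0.69). Dlx6 differed by 1.15 (SE 0.40), Gad2, which makes the transmitter GABA, by 1.07 (SE 0.40), and Slc32a1, its vesicle transporter, by 0.45 (SE 0.15). These values rested on knockdown replicate 2, without which Dlx5, Dlx6, Gad2 and Slc32a1 differed by 1.18, 0.62, 0.53 and 0.29. The list's score lay above all controls in each knockdown array, at 0.278, 1.198 and 0.256 for replicates 1, 2 and 3 (p = 0.0286 by the exact permutation test), and without knockdown replicate 2 the list still passed, with a mean of 0.27. By the median of the members instead of their mean, the groups overlapped, with 0.0775 in knockdown replicate 3 and 0.127 in control replicate 1. No member passed, over all genes or when adjusted over the list alone.

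In all, 13 of the 40 lists passed by camera with its preset correlation, 6 higher and 7 lower. By camera with an estimated correlation 0 lists passed (smallest adjusted p = 0.586), by fry for change in 1 direction 0 (smallest adjusted p = 0.113, with 2 lists at an unadjusted p under 0.05), and by exact permutation of the list scores 0 (smallest adjusted p = 0.381). The permutation test could pass a list only if many lists reached its smallest p of 0.0286, so its 0 says little. Without control replicate 4 the count by camera was 21. By fry in its mixed form, which asks for change in either direction, 7 lists passed (adjusted p between 0.00233 and 0.0434). These were the small RNA processing, axon guidance, cell cycle exit, cortical layer, histone, Polycomb and neuronal lists, of which 2 also passed by camera. That count was 0 without control replicate 1 or 3, 2 without control replicate 2, 11 without control replicate 4, and 1, 16 and 4 without knockdown replicates 1, 2 and 3. With the endothelial score as a covariate 4 lists passed, of which 2, the axon guidance and neuronal lists, were among the 7. With the endothelial score as a covariate the camera calls of pericytes, matrix, meningeal, ribosome biogenesis and intermediate progenitor genes ended. Those of intermediate progenitors, ribosome biogenesis and p53 targets ended without the dimmer 50% of genes, and those of intermediate progenitors, ribosome biogenesis and meningeal fibroblasts without the dimmest 25%. Against 10000 random lists of the same levels, the medians of the histone, G2 and M phase, p53 and oxidative phosphorylation lists lay at percentiles 0, 0, 0.57 and 2. Those of the 6 lists called higher lay between percentiles 99.1 and 100. Lists that were not called lay as far out, with the microglia, erythroid and X and Y-linked lists at 100, small RNA processing at 99.8, interferon response at 0.02 and hem and choroid plexus at 0.6, so these percentiles do not set the called lists apart. The 21 lists not described above had adjusted p values between 0.101 and 0.905 by camera and mean differences between -0.18 and 0.40. The mean, the median and the direction of the test differed in sign for 6 of these, the interferon, Notch, BAF complex, heat shock, apical junction and oligodendrocyte and astrocyte lists.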

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

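The split counts for genes past the threshold and for fry in its mixed form, and the tests of the vascular pattern, were chosen after the result was seen, while the other splits of the samples were planned.

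Control replicate 4 stood apart from the other controls in several groups of genes. Its endothelial list score was 1.626, against -0.681 to -0.376 in the other 3 controls, a gap of 0.868 of the range. Its meningeal fibroblast score was 0.566 against -0.239 to -0.131 (gap 0.866), and its score of hem and choroid plexus genes was 1.533 against -0.631 to -0.313 (gap 0.853). Its glycolysis and hypoxia score was 0.144 against -0.06 to -0.031 (gap 0.857), and its score of cytosolic ribosomal proteins was -0.18 against 0.041 to 0.073 (gap 0.873). The lowest correlation of this array with any other, across genes, was 0.951, against 0.959 to 0.961 for the other controls (gap 0.842). That value is its correlation with knockdown replicate 3, whose median correlation over probe sets was lower (0.9425) than that of control replicate 4 (0.9572), so it does not set control replicate 4 apart. In control replicate 1 the score of Cajal-Retzius cell genes was 0.114 against -0.045 to -0.027 (gap 0.885), and Def8 was 6.157 against 6.000 to 6.021 (gap 0.866). These gaps exceed 0.829, which chance exceeds in about 1 in 20 groups, and 8 of 68 groups tested did so where about 3.4 are expected. The groups all come from the same control arrays and are not independent, so the 2 counts do not test for an excess.

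The endothelial, mural and matrix lists were higher in knockdown samples, but control replicate 4 shared the high endothelial score. Different amounts of vascular cells in the sorted samples are a candidate explanation: the endothelial markers varied together within the groups (estimated correlation 0.891), and with the endothelial score as a covariate the matrix list differed by 0.133 (95% interval -0.232 to 0.498). Slc2a1, the most abundant marker, was at 10.03 in control replicate 4 and 10.54 in knockdown replicate 1, and Eng was at 8.21 and 8.58, while 6 of the 16 markers had a mean level over 6 and 1 is also in the glycolysis and hypoxia list. Microglia scores were also high in control replicate 4 (1.70) and knockdown replicate 2 (1.23), but 0.18 in knockdown replicate 1. Erythroid scores were 0.48, 0.60 and 0.07 in these 3 arrays, and 0.51 in knockdown replicate 3. A sort for fluorescent cells should remove endothelial cells, and the labels do not give its purity. An effect of the knockdown on vascular genes stays open, since the endothelial difference of 0.862 had a 95% interval from -1.17 to 2.90. Vascular genes that change together could also give the correlation and the covariate result, so these do not separate the 2 explanations.

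Splits of the 7 arrays into 4 and 3 show how often other groupings give as much. By limma 0 genes passed, so 35 of 35 splits had to give at least as many (highest other 1), and this count says nothing about chance. At an unadjusted p under 0.05, 6 of 35 splits gave at least the 1158 genes found, and the highest of the others was 2053, for control replicate 1 with knockdown replicates 1 and 3 against the rest. For lists passing by camera, 12 of 35 splits gave at least 13, and the highest of the others was 21, so chance is not excluded for either count. For lists passing fry in its mixed form, 2 of 35 splits gave at least 7, the other being control replicate 4 with knockdown replicates 1 and 3 against the rest (also 7), so chance is not excluded.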

How the results depend on the processing

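Cyclic loess normalization, the endothelial covariate and the removal of 2 arrays together were chosen after the data were seen, and the other alternatives were planned. Trnp1 was lower in knockdown samples in all 19 settings (-0.47 to -0.28, smallest adjusted p 0.292). No gene passed by limma in any setting, with 35556 probe sets tested singly, at an adjusted p under 0.1 or with 1.5-fold added; at an unadjusted p under 0.05 there were 439 higher and 719 lower. Of 118 named genes 10 changed direction in some setting.

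Of genes at unadjusted p under 0.05, higher ones numbered 231 with equal array medians, 182 (477 lower) without the dimmer 50%, which tests fewer genes, 800 (541 lower, an excess of higher genes) without control replicate 4 and knockdown replicate 3, and 1040 over probe sets. Leaving out 1 array gave 301 to 882 higher and 469 to 1522 lower, the highest without knockdown replicate 2. Lists passing numbered 7 after quantile normalization again, 8 after cyclic loess, 9 to 21 leaving out 1 array, and 0 with an estimated correlation or by fry for change in 1 direction. By fry in its mixed form 7 lists passed, and 0 to 16 leaving out 1 array. Dim signal over background limits what RMA values can show. Beyond fewer genes or arrays, the cause was not tested.

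Direction changed after quantile normalization again for Dbi (0.04098), Eomes (0.0537), radial glia (0.03496), neurons (0.08356), S phase genes (0.001529) and axon guidance genes (0.0004414). After cyclic loess it changed for Dbi (0.1614), Eomes (0.1063), radial glia (0.05002), neurons (0.08541), S phase (0.004601), axon guidance (0.008398) and Polycomb genes (0.005853). With the endothelial covariate it changed for Dbi (0.03359), Cxcr4 (-0.02155), Maf (-0.01416), Ramp2 (-0.2637), Igf2 (-0.4919), neurons (0.08957) and meningeal fibroblasts (-0.05506). For Neurog2 it changed with array weights (-9.338e-05) and equal medians (-0.0415). Without control replicate 4 and knockdown replicate 3 it changed for Il6st (0.2257), Neurog2 (-0.2935) and Map2 (-0.2308).

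Leaving out 1 array, the ranges that crossed 0 were -0.09733 to 0.03467 for Dbi, -0.03167 to 0.235 for Cdh4, -0.635 to 0.017 for Il6st, -0.2868 to 0.1113 for Eomes, -0.1833 to 0.4012 for Neurog2, -0.2035 to 0.2955 for Map2, -0.0965 to 0.2385 for Cxcr4, -0.0765 to 0.3543 for Maf, -0.3038 to 0.1695 for neurons and -0.2643 to 0.01841 for S phase genes. Of the list means, 283 values kept direction and side of the threshold, 67 no longer passed and 12 newly did. The robust prior was not run for lists, and the endothelial list has no value with its own score as covariate.

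With the replicate number as a block, Trnp1 differed by -0.37, Neurog2 by -0.124, and 0 genes and 22 lists passed (by fry in its mixed form 3, with 0 of the 7 that passed without the block), with 644 genes higher and 842 lower at an unadjusted p under 0.05. Number 4 occurs only in the controls, so control replicate 4 had a block of its own and added nothing to the difference. The block fit thus compared only the arrays whose number occurs in both groups. Its counts do not separate the block from the loss of control replicate 4. Without that array and without a block, 11 lists passed fry in its mixed form, 6 of them among the 7. The data gave no sign that the numbers pair the samples. Deviations of equally numbered arrays correlated at 0.0278, -0.0507 and 0.0716, all under 0.1, and 2 of 6 arrays correlated best with their own number. These values do not exclude a shared litter or day.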

Other observations

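The tests of the histone list and of the ventral forebrain list were chosen after the result was seen, and the split test of the smallest p over all lists was planned.

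Replication-dependent histones were lower in all 3 knockdown arrays, with scores of -0.60, -0.29 and -0.55 against -0.13 to 0.15 in the controls. After cyclic loess normalization, which evens out the average shift with level between arrays, the difference was -0.36 (95% interval -0.549 to -0.171). Such an average shift thus did not account for the whole difference. The interval takes no account of the choice of this list as the best of 40. With the S phase score as a covariate the histone difference was -0.422 (-0.599 to -0.245), against -0.478 (-0.787 to -0.169) without it. With the G2 and M phase score as a covariate it was -0.35 (-0.515 to -0.186). The S phase score thus did not account for the histone difference. Fewer cells in S phase are not excluded by this, since the S phase score itself differed little between the groups (-0.12). Its direction also varied between knockdown replicates 1, 2 and 3 (-0.27, 0.18 and -0.25). For this list 1 of 35 splits, the real one, gave a camera p as small (-log10 p 11.54, highest other 9.239). The list was however the best of 40, and 17 of 35 splits gave a smallest p over all lists as small (highest other 29.77, for control replicate 4 with knockdown replicates 1 and 2), so chance is not excluded for a list picked in this way. A lower level of histone transcripts after the knockdown is a hypothesis that these data leave open.

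Interneuron and ventral forebrain genes were highest in knockdown replicate 2, where Dlx5 was at 8.73 and Dlx2 at 8.48. Cells from the ventral forebrain in that array are a candidate explanation, and 7 of 15 dorsal cortical markers were at their lowest of the 7 arrays there, where chance gives 2.14. In knockdown replicate 3, whose ventral score was only 0.256, 6 of the 15 were at their lowest, so low dorsal markers were not particular to replicate 2. The count lies between the bounds set for the test, so it leaves the explanation undecided. Knockdown replicate 2 was also high in the lists of other cell types, with a hem and choroid plexus score of 0.55 (-0.61 and -0.48 in knockdown replicates 1 and 3) and a microglia score of 1.23 (0.18 and -0.22), and control replicate 4 was higher in both (1.53 and 1.699) with a ventral score of -0.087. An effect of the knockdown is a candidate too, since the difference was 0.2667 without knockdown replicate 2 and both remaining scores lay above all controls. That separation holds for the mean of the members only, as the median in knockdown replicate 3 (0.0775) lay below control replicate 1 (0.127). Of the 19 genes 1, Cxcr4, had a mean level over 6 (8.21), and 1 is in another list. These 2 explanations do not exclude each other.

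Knockdown replicates 1 and 3 shared high glycolysis and hypoxia scores (0.86 and 0.72) and low oxidative phosphorylation scores (-0.29 and -0.53), whereas knockdown replicate 2 was near the controls in both (-0.12 and 0.056). Replicates 1 and 3 also had the narrowest spread of values, with interquartile ranges of 3.12 and 2.98 against 3.17 to 3.34 in the other arrays. The oxidative phosphorylation call ended after a further quantile or a cyclic loess normalization. The G2 and M phase scores were -1.28, 0.24 and -0.56 in knockdown replicates 1, 2 and 3, against -0.58 to 0.44 in the controls. On the first principal component, with 27.8% of the variance, control replicate 4 was at 50.1 and the other arrays between -22.9 and 16.7. On the second principal component, with 25.4% of the variance, knockdown replicates 1 and 3 were at -36.1 and -37.5 and the other arrays between 7.07 and 26.5.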
